A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

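RNA of the budding yeast Saccharomyces cerevisiae, strain DS10, was measured on 3 one-colour NimbleGen expression arrays labelled with Cy3, 1 array for each of 3 plasmids. Per the labels, fresh transformants carried the low-copy plasmid pRS415 with the strong GPD promoter and either TAP (called vector here, whose product is not given in the sources used here), the Ssz1 protein with the substitution S295F, or residues 365 to 433 of Zuo1 with the substitution S427G. Cells grew to log phase in medium without leucine, which keeps the plasmid, and RNA was taken by hot phenol extraction. Per the series' design text, RNA from 3 cultures per plasmid was pooled before it was put on the array. Each group therefore has 1 array and no spread between cultures can be estimated, so no p-value was computed and every comparison is a comparison of these arrays.

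The array values are gene-level intensity values on a linear scale, deposited by the authors after RMA (background correction, normalization and a summary over a gene's probes). RMA is named in the submitters' processing notes, and its software and version are not given in the sources used here. Per the file headers, each of 5777 genes has 3 values on every array, 1 for each of 3 blocks, and up to 8 probes per gene (5406 genes with 8, 330 with 7 and 41 with fewer). Probe positions and values per probe were not used here. A second deposited column has no stated meaning and was not used. The series-wide value table holds the mean intensity over the 3 blocks for 5769 of these genes, with a largest relative difference of 3.33e-10 from the mean computed here, and served only as an alternative.

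The intensity of each block was put on the log2 scale and averaged over the 3 blocks, with no floor and no pseudocount. The log2 ratio of a gene is the difference of these means between arrays. An error given after a log2 ratio is the SD of that ratio over the 3 blocks. It covers technical noise within a pair of arrays and nothing between cultures, RNA preparations or hybridisations. Median block SDs of the ratios were 0.04 for each comparison. A gene is called higher or lower past 2-fold where its log2 ratio reached 1 in size, which is a rule of size and not a test. No further normalization was applied to the deposited intensities.

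Genes are named through a RefSeq gene table of the current yeast assembly, matched by locus tag for 5771 genes, and 6 kept the array's name. Coordinates are those written in the array files, which refer to chromosome sequences of 2008 and give the span of the coding sequence from start to stop codon. These lengths hold no untranslated parts and are called coding length.

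Choices made before the data were examined were the size rule, 43 gene lists, the rule for naming genes and most alternatives. The rule named SSZ1 and ZUO1 first, with TDH3 (whose promoter is the GPD promoter) and LEU2 (the plasmid marker). It then took the 12 genes with the highest and the 12 with the lowest log2 ratio in each comparison with vector, among genes past 2-fold whose brighter array of the pair was at or above the 25th percentile of that array, and 6 in each direction for the comparison of the 2 constructs. Up to 4 members with the largest ratios could be named for each list described, and every member of the drug resistance list. The part of the rule on the sign of single probes did not apply, since values per gene were used. Genes named outside this rule are said to be so. The ribosomal protein list was built from gene names and so also took RPP1, a subunit of RNase P.

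For each list, the median log2 ratio was set against 10000 random lists of the same size matched on mean level in 10 strata. A list is called outside where its median lay outside the central 95% of the random lists, that is below the 2.5th or above the 97.5th percentile. With 43 lists, 2.15 per comparison would lie outside by chance if lists were independent, and genes of one list are not independent of each other. The percentile describes these arrays and is not a test between conditions. After a trend with coding length was seen, the same was done with random lists matched on mean level in 5 strata and coding length in 4, and each list's percentile from that matching is given where it differs in its call.

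Both comparisons with vector use 1 vector array. Correlation, covariance, overlap and the share of genes with the same sign were therefore set beside 100 simulated sets of 3 unchanged arrays. The noise variance was the same for each array and was taken from the comparison of the 2 construct arrays. The overlap was also set beside that of independent lists. The vector group cannot be split, having 1 array.

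Alternatives planned before the data were examined were the series-wide table, ratios centred on their median, a further quantile normalization, a loess of the ratio on mean level, leaving out the lowest 25% of genes by level, thresholds of 1.5-fold and 3-fold, leaving out families with near-identical copies, 20 strata and list means. Those added after the data were seen were the median over blocks, each block alone, a loess on coding length and matching on coding length. The loess used a span of 0.4 and 3 robust iterations. The steps were tested on simulated arrays of 5777 genes for the comparison of Ssz1 S295F with vector. Of 102 genes shifted by a log2 size of 1.5, 98.0% were recovered past 2-fold, and of 98 shifted by 3, 100% were. None of the 5577 unchanged genes passed, and 3.5% of 200 unshifted lists fell outside the central 95%. The simulated noise was the same at every level, with no length trend and no changes shared within lists. These figures check the steps and are not error rates for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.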

Results

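Transcript levels of yeast genes were compared between cells carrying the vector, cells expressing Ssz1 S295F and cells expressing residues 365 to 433 of Zuo1 with S427G, with 1 array of pooled RNA per group. Ssz1 is an Hsp70-type protein and Zuo1 a J-protein that together form the ribosome-associated complex, a chaperone of nascent chains. Both are also known as activators of the transcription factor Pdr1, which drives genes of pleiotropic drug resistance, and the comparisons ask which transcripts change when the mutant protein or the C-terminal fragment is expressed. The median intensity was 2802 on the vector array, 2697 on the Ssz1 S295F array and 2722 on the Zuo1 fragment array, and gene values ran from 3.77 to 41706 over the arrays. The blocks of an array correlated at 0.998 or more across genes. Across genes, log2 levels of the 2 construct arrays correlated at a Pearson r of 0.994, while the vector array correlated at 0.947 with the Ssz1 S295F array and at 0.967 with the Zuo1 fragment array. No array was repeated, so no difference below has a replicate check.

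The genes on the plasmids came first. SSZ1 (YHR064C, chromosome VIII, 225527 to 227143) had an intensity of 10279 with vector, 19318 with Ssz1 S295F and 12001 with the Zuo1 fragment, so its log2 ratio to vector was 0.91 ± 0.07 with its own construct and 0.22 ± 0.05 with the other (SD over 3 blocks, here and for each ratio below). ZUO1 (YGR285C, chromosome VII, 1061859 to 1063160) read 13337, 13744 and 12935 on the same arrays. The fragment holds 69 of the 433 residues of Zuo1, or 15.9%. As the places of the ZUO1 probes were not used here, its reading does not check the fragment. TDH3 was near the top of the range on each array, at 40459, 39255 and 40677. The plasmid marker LEU2 read 20669, 17711 and 18998.

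With Ssz1 S295F, the list of Pdr1 and Pdr3 targets had a median above all random lists, and the hypoxic, PAU, pheromone response and mitochondrial ribosomal lists had medians below all of them. Past 2-fold, 290 genes were higher and 160 lower, of which 251 and 129 passed in every block. The median ratio of all genes was -0.15, so the middle gene lay slightly below vector. With the ratios centred on that median, 394 genes were higher and 90 lower. At least 1 reading of the pair lay below the 5th percentile of its array for 56 of the 290 and 68 of the 160 genes, and the sizes of such ratios are uncertain beyond their block SD.

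The list of 20 targets of Pdr1 and its relative Pdr3 had a median log2 ratio of 0.73 with Ssz1 S295F, above all 10000 random lists, and 7 members passed 2-fold. These were RSB1, a transporter of sphingoid bases (1.90 ± 0.02), ICT1, a lysophosphatidic acid acyltransferase (1.89 ± 0.03), the reductase gene GRE2 (1.63 ± 0.07), YGR035C (1.56 ± 0.02), the ABC transporter YOR1 (1.28 ± 0.04), CIS1 (1.24 ± 0.01) and the polyamine transporter TPO1 (1.08 ± 0.00). PDR5, the main multidrug ABC transporter (YOR153W, chromosome XV, 619841 to 624376), read 9653 with vector and 17493 with Ssz1 S295F, a log2 ratio of 0.86 ± 0.04 that did not reach 2-fold. SNQ2 (0.62 ± 0.01), PDR16 (0.75 ± 0.04), LAF1 (0.90 ± 0.06) and IPT1 (0.70 ± 0.08) lay in the same range. PDR10 (-0.39 ± 0.04) and YLL056C (-0.54 ± 0.02) were below vector, PDR15 was at -0.10 ± 0.08, and HXT9 (0.43), HXT11 (0.16), RTA1 (0.38), BDH2 (0.41) and PDR3 (0.36) stayed under 1. PDR1 itself, named outside the rule, was at 0.17 ± 0.01. Drug-response regulators as a list had a median of 0.32 (99.0th percentile) and multidrug transporters of the major facilitator family 0.28 (99.7th percentile), but among random lists matched on coding length too they lay at the 87.9th and 92.6th percentiles.

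**Figure D1:**
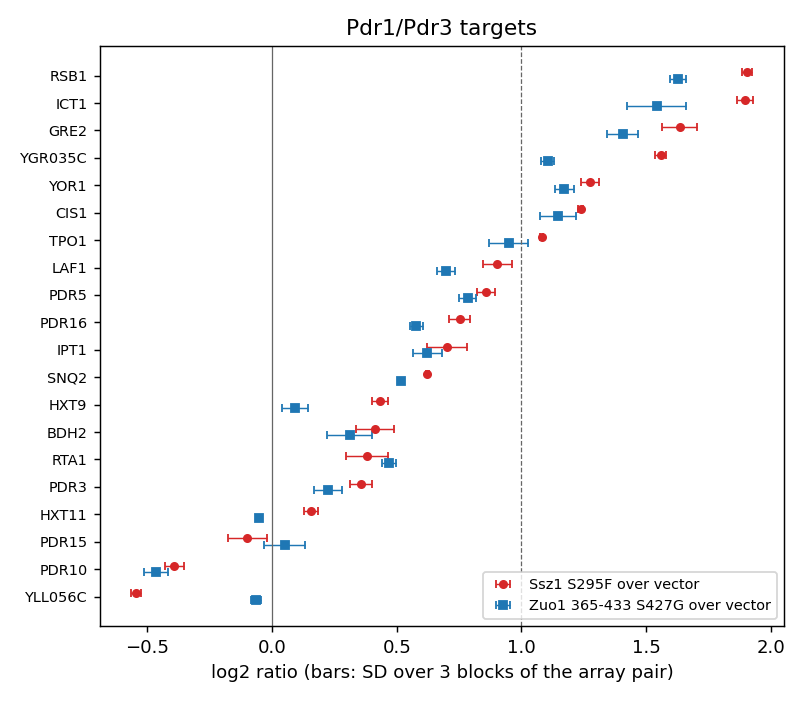
Log2 intensity ratios of the 20 Pdr1/Pdr3 targets (horizontal axis) for each construct over vector, as circles for Ssz1 S295F and squares for the Zuo1 fragment, with the SD over 3 blocks of the array pair as bars and the 2-fold line dashed. In the plot 7 targets lie past 2-fold with Ssz1 S295F and 6 with the Zuo1 fragment, and PDR10 and YLL056C lie below 0 with both.

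Genes of hypoxic and anaerobic growth had a median of -0.85 with Ssz1 S295F, below all random lists, and 5 of 12 passed 2-fold. The largest differences on the lower side of the comparison were in this list. DAN1, a mannoprotein of anaerobic cell walls, read 1561 with vector and 18.7 with Ssz1 S295F (-6.38 ± 0.09, with the Ssz1 S295F reading below the 5th percentile of its array, so the size is uncertain), and TIR1, of the same class, read 6753 and 408 (-4.05 ± 0.12). TIR3 was at -1.73 ± 0.06 and COX5B, a cytochrome oxidase subunit used at low oxygen, at -1.13 ± 0.04. The related PAU (seripauperin) family had a median of -1.08 and 13 of its 21 measured members passed 2-fold, with the largest difference in PAU20 (-1.25 ± 0.10). PAU genes are near-identical to each other, so their single values are uncertain.

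The pheromone response list had a median of -0.69, below all random lists, with 1 of 12 members lower and 1 higher past 2-fold. FIG1 was at -2.85 ± 0.18 (with a reading below the 5th percentile), FIG2 at -0.99 ± 0.08 and FUS2 at -0.97 ± 0.07, while STE12, the transcription factor of the pathway, was higher at 1.13 ± 0.08. Genes specific to MATa cells had a median of -0.34 (0.14th percentile) and haploid-specific genes -0.38 (2.4th percentile), with 0 of 7 past 2-fold in each, and MATalpha-specific genes were inside the range (64.5th percentile). The call for MATa-specific genes was lost once a loess on coding length was subtracted (5.55th percentile), and that for haploid-specific genes was lost under 6 of 14 other settings, among them quantile normalization (9.2nd percentile), block 1 alone (3.85th) and the loess on mean level (12.3rd). The zinc regulon (-0.45) lay at the 0.4th percentile with no member past 2-fold, and its largest difference was in the zinc transporter ZRT1 (-0.97 ± 0.02). Mitochondrial ribosomal proteins had a median of -0.52, below all random lists matched on level and at the 0.1st percentile with coding length matched too, with 0 of 66 lower and 1 higher past 2-fold.

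Some list calls ended once coding length was matched. Cytosolic ribosomal proteins (median -0.18) lay below all random lists matched on level, and histones (-0.25) at the 0.37th percentile. With coding length matched they were at the 44.6th and 14.9th percentiles. Hexose transporters (0.12, 98.9th percentile) were at the 68.1st percentile in that matching, with HXT13 (1.63), HXT8 (1.63) and HXT17 (1.61) higher and HXT4 lower (-1.78). The vector readings of HXT13, HXT8 and HXT17 lay below the 5th percentile, and the near-identical members of this family are uncertain. G2/M cell cycle genes (0.22) were at the 98.3rd and then the 91.8th percentile, with the cyclin CLB2 at 1.97 ± 0.05. Amino acid biosynthesis genes (0.03) were at the 98.8th and then the 96.2nd percentile. Over the 14 other settings, the call was lost under 6 for hexose transporters, 5 for amino acid biosynthesis, 4 for drug-response regulators and G2/M genes, and 2 for ribosomal proteins and histones.

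Among all genes, the highest ratios with Ssz1 S295F that met the naming rule were of PTH1, a mitochondrial peptidyl-tRNA hydrolase (4.60 ± 0.12), MET13, a methylenetetrahydrofolate reductase (3.78 ± 0.04), GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase (3.23 ± 0.13), the kinase gene YPK2 (3.10 ± 0.04) and CAN1, the arginine permease (3.08 ± 0.07). VAM10 (an intensity of 636 with vector and 5073 with Ssz1 S295F), TVS1 (2.94), AQY3 (2.87), FRE5 (2.82), ATG15 (2.80), RIM20 (2.79) and AMF1 (2.79) followed. The vector readings of PTH1 and FRE5 lay below the 5th percentile of that array. VAM10 overlaps VPS5, and their signals were not separated. On the lower side, ARO10, a decarboxylase of amino acid breakdown (-2.25 ± 0.06), PRM7 (-1.87 ± 0.05), the repressor gene NRG2 (-1.65 ± 0.04), YLR297W (-1.60 ± 0.13), the stress gene DDR2 (-1.49 ± 0.05), glycogen phosphorylase GPH1 (-1.47 ± 0.13), TDA6 (-1.46 ± 0.06) and YDR222W (-1.40 ± 0.02) joined DAN1, TIR1, TIR3 and HXT4. PRM7 overlaps YDL038C. Of the 290 higher genes 37 belonged to any of the 43 lists, and of the 160 lower genes 37 did.

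With the Zuo1 fragment, the Pdr1 and Pdr3 targets again had a list median above the random range and the hypoxic, PAU and pheromone response lists medians below it, each smaller in size than with Ssz1 S295F. Haploid-specific genes (12.5th percentile), histones (3.12th), hexose transporters (93.8th) and amino acid biosynthesis genes (77.5th) were inside the random range here. Past 2-fold, 210 genes were higher and 50 lower than with vector, 185 and 41 of them in every block, with a median of all genes of -0.12. Centred on that median, 252 were higher and 31 lower. Targets of Pdr1 and Pdr3 had a median of 0.60, again above all random lists, and 6 passed 2-fold: RSB1 (1.63 ± 0.03), ICT1 (1.54 ± 0.12), GRE2 (1.41 ± 0.06), YOR1 (1.17 ± 0.04), CIS1 (1.15 ± 0.07) and YGR035C (1.10 ± 0.03). TPO1 was at 0.95 ± 0.08 and PDR5 at 0.78 ± 0.04, with an intensity of 16620. SNQ2 was at 0.52 ± 0.01 and PDR10 at -0.46 ± 0.05. Drug-response regulators (0.19, 98.8th percentile) and multidrug transporters of the major facilitator family (0.24, 99.9th percentile) were at the 84.3rd and 95.2nd percentiles with coding length matched.

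Hypoxic and anaerobic genes had a median of -0.73 with the Zuo1 fragment, below all random lists, and 4 of 12 passed 2-fold: DAN1 (-3.49 ± 0.06, intensity 139 and below the 5th percentile), TIR1 (-1.81 ± 0.01, intensity 1922), TIR3 (-1.30 ± 0.09) and DAN4 (-1.23 ± 0.03). PAU genes had a median of -0.63 (0.01th percentile) with 2 of 21 past 2-fold, PAU3 (-1.12 ± 0.13) and PAU21, for which no size is given as both readings lay below the 5th percentile. This PAU call was lost after the loess on coding length (11.05th percentile). The pheromone response list (-0.44, 0.02th percentile) had 1 of 12 members lower past 2-fold, FIG1 (-1.72 ± 0.04, with a reading below the 5th percentile), and 1 higher, STE12 (1.06 ± 0.01). The zinc regulon had a median of -0.43, below all random lists, with 0 of 8 past 2-fold. Mitochondrial ribosomal proteins had a median of -0.37, below all random lists and at the 1.02nd percentile with coding length matched, with 0 of 66 lower and 1 higher past 2-fold. MATa-specific genes (-0.22, 0.63rd percentile, 0 of 7 past 2-fold) changed side of the median of all genes after the loess on coding length. The thiamine list was outside with this construct only (-0.59, 0.94th percentile, against -0.28 and the 50.2nd with Ssz1 S295F), with THI2 at -0.82 ± 0.02 and THI13 at -0.74 ± 0.03, but without the lowest 25% of genes by level its call was lost (12.2nd percentile). Cytosolic ribosomal proteins had a median of -0.09, below all random lists matched on level but at the 99.6th percentile with coding length matched. G2/M genes (0.21, 99.2nd percentile, CLB2 at 1.87 ± 0.06), genes of cell separation after mitosis (0.18, 99.2nd percentile) and the iron regulon (0.02, 97.6th percentile) were inside the range with coding length matched, at the 95.7th, 97.1st and 89.9th percentiles.

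The genes highest by the naming rule with the Zuo1 fragment were MET13 (3.49 ± 0.03), CAN1 (2.85 ± 0.20), VAM10 (2.71 ± 0.02), TVS1 (2.60 ± 0.03), YPK2 (2.59 ± 0.03), RIM20 (2.56 ± 0.06) and GUT2 (2.55 ± 0.14). YCK3 (2.51), ATG15 (2.41), RPR2 (2.39), GEM1 (2.28) and AQY3 (2.28) completed the 12. Besides DAN1, TIR1 and TIR3, the lowest were ARO10 (-1.43 ± 0.05), TDA6 (-1.37 ± 0.01), the methyltransferase gene MHT1 (-1.29 ± 0.06), YCL021W-A (-1.27), YLR297W (-1.17), PRM7 (-1.16), GPH1 (-1.04), NRG2 (-1.04) and YHL026C (-1.02). In the lists, 23 of the 210 higher genes and 12 of the 50 lower genes were found.

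**Figure D2:**
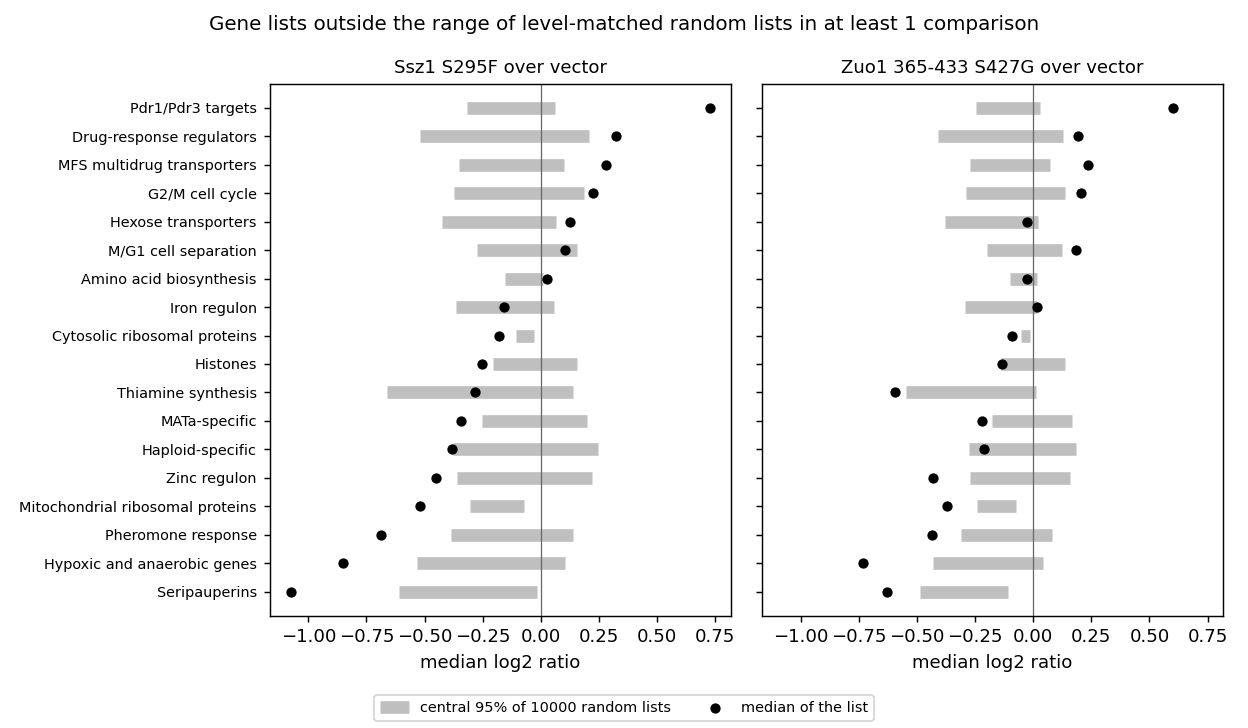
Median log2 ratio over vector (horizontal axis) of each list that lay outside the central 95% of random lists matched on mean level in at least 1 comparison, as black points, beside that central range as grey bars, for Ssz1 S295F on the left and the Zuo1 fragment on the right. Pdr1/Pdr3 targets stand highest at 0.73 and 0.60, and the PAU list stands at -1.08 and -0.63.

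The lists of Yap1 targets, ribosome-associated chaperones, Hsf1 chaperones, Msn2/Msn4 stress genes, glycolysis, gluconeogenesis, the tricarboxylic acid cycle, oxidative phosphorylation, peroxisomal oxidation, ribosome biogenesis, the leucine pathway, sulfur assimilation, phosphate starvation, nitrogen catabolite repression, ergosterol, sphingolipids, the unfolded protein response, the proteasome, G1/S genes, trehalose and glycogen, cell wall, stationary phase, purine synthesis, MATalpha-specific genes and meiosis, 25 in all, stayed inside the central 95% in both comparisons with vector. Their medians ran from -0.27 to 0.06 with Ssz1 S295F and from -0.45 to 0.05 with the Zuo1 fragment. Single members still passed 2-fold with Ssz1 S295F, among them SHM2, a serine hydroxymethyltransferase (2.29 ± 0.04), and the phosphatase gene PHO8 (1.75 ± 0.05), which were at 2.07 and 1.66 with the Zuo1 fragment. Among random lists matched on coding length too, oxidative phosphorylation lay above all random lists in both comparisons and cell wall genes at the 98.18th and 98.04th percentiles, and ribosome biogenesis lay at the 0.15th percentile with Ssz1 S295F.

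The ratios of the constructs to vector went together across genes. Past 2-fold in both comparisons, 207 genes were higher and 44 lower, and 0 genes went past 2-fold in opposite directions. Independent lists would share 10.5 and 1.38, but these lists share the vector array and are not independent. The simulated sets held 0 and 0, but their noise, with an SD of 0.147 for every gene, left 2-fold out of reach. The comparison of the 2 construct arrays, which gave this noise, had 8 higher and 8 lower genes past 2-fold. These simulated counts therefore decide nothing. The ratios correlated across genes with a Pearson r of 0.954 and a Spearman rho of 0.930, where genes are not independent replicates. A shared vector array with the same noise as the other arrays gave a simulated r of 0.4997. The covariance was 0.280 against a simulated 0.0215, a difference of 0.259. The same sign was seen in 92.1% of genes, against 66.7% simulated. The single vector array enters both comparisons and was not split, having no replicate. A vector array that deviated more than the others would by itself raise these values above the simulated ones. They therefore do not tell a response to both constructs from a deviation of the vector array. Of the 207 genes higher in both, 194 had the larger ratio with Ssz1 S295F, as did 39 of the 44 lower genes in size.

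**Figure D3:**
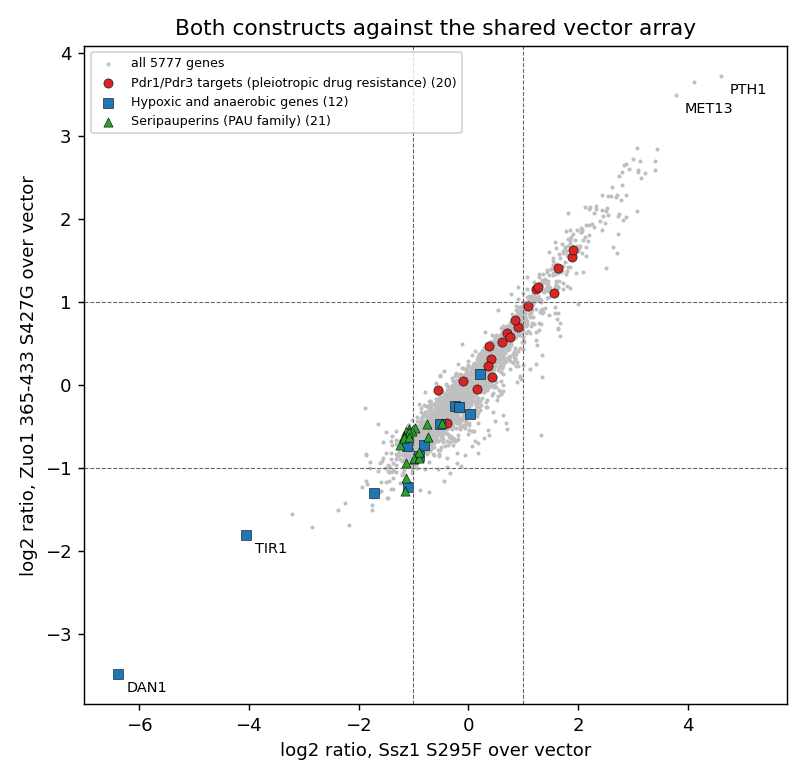
Log2 intensity ratio of each gene with Ssz1 S295F over vector (horizontal axis) and with the Zuo1 fragment over vector (vertical axis), which share the vector array. Dashed lines mark 2-fold, and coloured symbols mark 20 Pdr1/Pdr3 targets, 12 hypoxic and anaerobic genes and 21 PAU genes, with DAN1 farthest down at -6.38 and -3.49.

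Ratios to vector also went with coding length, in both comparisons. Their Spearman correlation with coding length across genes was 0.552 with Ssz1 S295F and 0.516 with the Zuo1 fragment. The shortest 20% of genes, up to 654 bp, had medians of -0.48 and -0.34, and genes of 1461 to 2115 bp had medians of 0.11 and 0.08. With Ssz1 S295F, 106 of the 160 lower genes were among the shortest 20% and 124 of the 290 higher genes had 1461 to 2115 bp. The correlation with coding length was -0.413 for the Zuo1 fragment over Ssz1 S295F, so the trend was also present without the vector array.

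**Figure D4:**
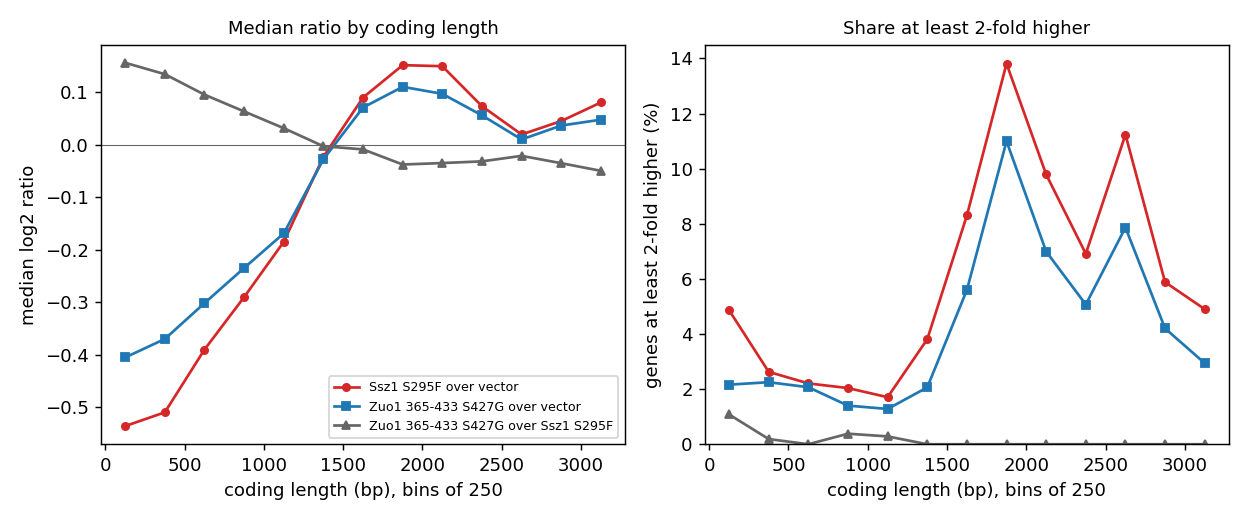
Median log2 ratio (left) and percent of genes at least 2-fold higher (right) by coding length in bins of 250 bp that hold at least 100 genes, for each of the 3 comparisons. The share higher with Ssz1 S295F is 13.8% at 1751 to 2000 bp and 1.71% at 1001 to 1250 bp.

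The construct arrays differed little from each other. Past 2-fold, 8 genes were higher and 8 lower with the Zuo1 fragment than with Ssz1 S295F, and 1 of them met the naming rule, TIR1, at 2.23 ± 0.12. DAN1, PRM6, SPS4, SIP18 and FIG1 read higher with the Zuo1 fragment and CDA1 and STE3 lower, all named after their values were seen. Both readings of each lay below the 5th percentile of their array, so no sizes are given. In all, 7 of the 8 higher and 4 of the 8 lower genes had both readings there, and 5 of the 8 lower genes had at least 1. SSZ1 was at -0.69 ± 0.02.

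Pdr1/Pdr3 targets were slightly lower with the Zuo1 fragment than with Ssz1 S295F, with a median of -0.12 (0.01th percentile) and 0 of 20 past 2-fold. The largest differences were in YGR035C (-0.45 ± 0.01) and, in the other direction, YLL056C (0.48 ± 0.01), and PDR15 (0.15) and RTA1 (0.09) were higher as well. PAU genes were higher (0.45, above all random lists), as were pheromone response genes (0.28, above all). Ribosome biogenesis (0.09), the iron regulon (0.13), haploid-specific (0.16) and MATa-specific genes (0.12) were higher at the 99.3rd percentile or above. Amino acid biosynthesis (-0.06), the tricarboxylic acid cycle (-0.09), purine synthesis (-0.09) and cell wall genes (-0.03) were lower, at the 0.8th percentile or below. With coding length matched, multidrug transporters of the major facilitator family (2.12th and then 15.4th percentile), gluconeogenesis (1.06th and 3.89th), trehalose and glycogen (0.56th and 8.08th) and mitochondrial ribosomal proteins (100th and 96.9th) came to lie inside the range, and oxidative phosphorylation (16.9th and 0.02th) outside it. The hypoxic list as a whole was at the 51.3rd percentile, although DAN1 and TIR1 differed. In all, 25 of the 43 lists lay outside the central 95%, 11 of them under each of 14 other settings, and 0 of 43 had a median past 2-fold. PAU genes are among the 11, but the setting without families of near-identical copies leaves them out and is no check of their list.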

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

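The median over blocks, each block alone, the loess on coding length and matching on coding length were chosen after the data were seen. No paired analysis was possible because each group has 1 array, and for the same reason no replicate was left out in turn. The planned median over single probes was not run, since values per gene were used. Genes near the floor of the arrays limit the counts, as the values without the dimmest genes show.

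Lower genes depended on scaling more than higher genes. Centring gave 90 lower genes with Ssz1 S295F, 31 with the Zuo1 fragment, 14 between the constructs and 26 lower in both comparisons with vector. A further quantile normalization gave 82, 29 and 22 for Ssz1 S295F, the Zuo1 fragment and both. The loess on mean level gave 443 higher genes with Ssz1 S295F, with 39 and 15 lower genes in the comparisons with vector, 21 between the constructs and 13 in both. The loess on coding length gave 52 and 19 lower, 14 between the constructs and 16 in both. Block 2 alone gave 15 lower genes between the constructs. The counts after centring follow from the medians of all genes that it subtracts, -0.15, -0.12 and 0.03 for Ssz1 S295F, the Zuo1 fragment and between the constructs. For the other settings the cause was not tested. Without the lowest 25% of genes by level, which tests fewer genes, 173 were higher and 22 lower with Ssz1 S295F, 127 and 8 with the Zuo1 fragment, 1 and 0 between the constructs, and 126 and 6 in both. By the construction of the threshold, 1.5-fold gave 592 and 755, 439 and 414, 39 and 80, and 434 and 360 in the same order, and 3-fold gave 135 and 25, 91 and 4, 4 and 1, and 90 and 4.

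The correlation of the ratios to vector was 0.956 after quantile normalization, 0.958 after the loess on mean level, 0.967 without the dimmest genes, 0.955 without families of near-identical copies, 0.953 with the median over blocks, 0.950, 0.951 and 0.950 for blocks 1, 2 and 3 alone and 0.945 after the loess on coding length.

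The number of lists outside the central 95% stayed within 1.5 times its main value under every setting, but not the same lists. Of 15 lists with Ssz1 S295F, 6 stayed outside on the same side under each of 14 other settings, and of 14 lists with the Zuo1 fragment, 5 did. Pdr1/Pdr3 targets, hypoxic genes, pheromone response, the zinc regulon and mitochondrial ribosomal proteins are in both sets, and PAU genes in the first only. The setting without families of near-identical copies leaves PAU genes out, so it is no check of their list. The list medians that changed side, given as their difference from the median of all genes, were cytosolic ribosomal proteins with the Zuo1 fragment (-0.0091 after quantile normalization, -0.0633 after the loess on mean level, -0.0059 without the dimmest genes) and with Ssz1 S295F (0.135 after the loess on coding length), MATa-specific genes with the Zuo1 fragment (0.0235 after the loess on coding length) and histones with Ssz1 S295F (0.259 after it). Between the constructs they were glycolysis (-0.0064 after quantile normalization), Msn2/Msn4 genes (-0.0565), hexose transporters (0.0261) and thiamine synthesis (0.0491) without the dimmest genes, and histones (-0.0228) after the loess on coding length. The cause was not tested. Of the 24 genes named by rank with Ssz1 S295F, all present stayed past 2-fold in the same direction under each setting, except that 23 did after the loess on coding length. Of the 24 with the Zuo1 fragment, 21 did after centring, quantile normalization or the loess on mean level, 19 after the loess on coding length and 23 in block 3 alone.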

Other observations

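The tests of a function-blind difference of the vector array, of held-out blocks, of the size of the trend with level, of a graded difference between the arrays and of coding length for the hypoxic list alone were chosen only after the result was seen. The 18 genes encoded in mitochondrial DNA had medians of 0.75 with Ssz1 S295F and 0.67 with the Zuo1 fragment, with 17 and 18 of them above the median gene, 6 and 5 higher past 2-fold, and a median of 0.00 between the constructs. The intron-encoded reading frames AI2 (2.75 and 2.06) and AI3 (3.41 and 2.58) had the largest ratios, while COX1 was at 0.47 and 0.51 and OLI1 at -0.20 and 0.04. This set was chosen after its values were seen and was not set against random lists.

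Within the lists, the thiamine genes split between the constructs. The near-identical genes THI5, THI11, THI12 and THI13 had a median of 0.21 with Ssz1 S295F and -0.66 with the Zuo1 fragment, and the 4 hexose transporter genes HXT8, HXT10, HXT13 and HXT17 of 1.62 and 0.68. Both sets were chosen after their values were seen, and signal shared between their copies was not examined.

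Targets of Pdr1 and Pdr3 were higher with both constructs. All random lists matched on level and coding length lay below the list median in both comparisons (percentile 100), which argues against coding length. An intensity trend is argued against by its size, at most 0.12 above the median of all genes at any member, while the planned test (a lower median of 0.74 after the loess on mean level) decides nothing, as the loess lay below 0 at each member. A technical difference of the vector array that took genes at random, or by level and coding length alone, would give random lists of like level and length as many members past 2-fold in both comparisons. Of 10000 such lists, 0.02% held as many (6 members here, 0.775 on average), a count that is not independent of the list's percentile. A technical difference that went with another property of the genes, such as the sequence of their probes, was not examined and stays open. A difference in RNA quality or labelling graded over the 3 arrays was not tested for this list. Between the constructs the list had a median of -0.12, with 3 of 20 members above the median gene. Such a difference or a smaller response to the Zuo1 fragment would both give this. That both proteins raise Pdr1-dependent transcripts is a hypothesis not tested here, which repeat arrays with and without PDR1 would test, and 1 array per group cannot exclude a difference between the pooled cultures.

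The 207 genes higher past 2-fold with both constructs are the largest pattern. Noise of single spots is argued against, as at least 90.5% of the genes chosen in 1 block passed 2-fold in the mean of the others, while the 87.0% of the 207 that passed in each block fell short of the 95% set beforehand. The 94.2% that stayed past 2-fold after the loess on coding length decides little. The highest median ratio by coding length lay far below the log2 ratio of 1 set for 2-fold. In bins of 250 bp the median ran from -0.54 to 0.15 with Ssz1 S295F and from -0.405 to 0.11 with the Zuo1 fragment. The medians of all genes were -0.15 and -0.12. The highest bin medians argue against a shift of the median as the whole cause. The share past 2-fold also went with coding length, and this was not tested. A trend with level is argued against by its size of at most 0.11 above the median of all genes. The 100% that stayed after the loess on level decides nothing, as that loess lay below 0 at each gene. A difference in RNA quality or labelling that is strongest for the vector array and intermediate for the Zuo1 fragment array may account for them. It would give larger ratios with Ssz1 S295F, as 93.7% of these genes had. A smaller response to the Zuo1 fragment would give the same value, so a biological response stays open. The share of genes higher with Ssz1 S295F peaked at 13.8% at 1751 to 2000 bp of coding length, and the cause of this peak was not tested. Repeat arrays of the vector RNA could check labelling only, and a difference in RNA quality would need newly prepared RNA.

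For hypoxic, anaerobic and PAU genes, lower with both constructs, coding length is argued against in the hypoxic list (percentile 0.0 at most), and signal shared between PAU copies was not examined. An intensity trend is argued against as the whole cause only, as the loess on mean level took the list median with the Zuo1 fragment from -0.73 to -0.42, just past the -0.4 set beforehand, and left it at percentile 0.0. For PAU genes coding length cannot be told apart from a response, since the highest percentile was 0.245 with matched random lists but 11.05 after the loess with the Zuo1 fragment. A graded difference in RNA quality or labelling cannot be told apart either. Among the 5 hypoxic members past 2-fold, the log2 ratio with the Zuo1 fragment was at the median 0.657 of the log2 ratio with Ssz1 S295F. This lies below the quartiles of 0.746 and 0.912 for the genes past 2-fold higher, but the 5 members ran from 0.448 to 1.12. The 13 PAU genes past 2-fold had a median of 0.554 and quartiles of 0.529 and 0.585. That goes against a single shared factor for most of these PAU genes but rests on near-identical copies. DAN1 and PAU21 enter these values with readings below the 5th percentile, so their sizes are uncertain. These genes are known to respond to oxygen, and a difference in aeration or density between the cultures may equally account for their lower level and was not tested.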
